A study of Mus musculus with 2 samples.

How the data were processed

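H3K27me3, the trimethylated form of histone H3 lysine 27 that Polycomb repressive complex 2 deposits, was measured by chromatin immunoprecipitation and sequencing in mouse forebrain at embryonic day 13.5. The series held 1 group with 2 biological replicates, and the labels described the tissue as pooled from male and female embryos. It held no second condition, and only lists of called peaks were used here. The signal tracks that the accompanying descriptions list were not used here.

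Peak lists were deposited for replicate 1, for replicate 2, for both replicates together (the pooled list) and as replicated peaks (the replicated list). Per the descriptions deposited with the samples, each replicate's list combined its 2 technical replicates and was called on the mouse build mm10. The list of replicate 1 was derived from its alignment and 2 further files, and that of replicate 2 from its alignment and 1 further file, per the same deposited descriptions. The roles of these further files were not stated. The replicated list was derived from the other 3 lists by a rule not given in the sources used here. The aligner, the peak caller and its threshold were likewise not given in the sources used here.

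The deposited peaks carried a signal value, whose formula was not stated, and the −log10 p-value and −log10 q-value of each peak, per the file type named in the deposited descriptions. The design had assumed that the signal value was a fold enrichment. Because no source stated this, it was used only to rank and describe peaks. The lowest −log10 p-value of a list was 2.01 to 2.03, and the lowest −log10 q-value 0.317 to 0.519. The lists as deposited thus include peaks with weak q-values. Of the 51000 replicated peaks, 49841 had a −log10 q of at least 2. Read counts were not used here, so the depth of the libraries is unknown and no interval or detection limit that needs counts was given.

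Peaks on chromosomes 1 to 19 and X were compared with the GRCm38 genome sequence and the GENCODE vM21 annotation of the same build. Coordinates were written counting from 1. A gene was called marked when a replicated peak overlapped the 1 kb on either side of its 5′ end by at least 1 bp. The 5′ end was the outermost annotated start of the gene. For genes with read-through transcripts, such as Hoxa3 and Hoxc5, it lies far from the usual start. How many genes this affects was not examined. The covered share of a gene's window was the percentage of the 10 kb around the 5′ end (5 kb on either side) under a peak, taken in each replicate and averaged. Promoters were classed by the observed over expected frequency of CpG within 0.5 kb of the 5′ end. Values of at least 0.6 were called CpG rich and values under 0.4 CpG poor. Replicated peaks separated by gaps of 3 kb or less were merged into domains.

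Peaks were called shared when they overlapped a peak of the other replicate by at least 1 bp. Chance overlap was taken from 100 circular shifts of the peaks within each chromosome, leaving out the first 3 Mb of the chromosome sequence. Spearman correlations were computed across shared peaks, which are not independent replicates, and therefore carry no p-value.

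The 22 gene lists were Hox genes, forebrain patterning and neurogenic factors, midbrain, hindbrain and spinal cord factors, mesoderm, limb and muscle factors, endoderm factors, blood lineage factors, neuronal differentiation genes, glial genes, endothelial genes, erythroid genes, microglia and macrophage genes, meningeal and mesenchymal genes, housekeeping genes, secreted Wnt, Bmp, Fgf and Hedgehog ligands, pluripotency genes, germline genes, cell cycle inhibitor genes, Polycomb subunit genes, imprinted genes, olfactory receptors, keratins with keratin-associated proteins, and homeobox-type transcription factors outside the Hox list. Each was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 22 lists, at a threshold of 0.05. Genes are not independent replicates, so these p-values describe the lists and not the variation between embryos. Of the listed symbols, Ahsp had no match in the annotation. The homeobox list was built from gene symbols and also took in Arxes1, Arxes2, Islr and Islr2, which are not homeobox genes. The Fisher test and the test on CpG-matched lists were tested on simulated data with 100 lists of 40 genes at each planted share. Lists planted at the background share of 18.9% gave 3 calls by either test. Lists planted at 40% gave 84 calls by the Fisher test and 79 by the matched test, and lists planted at 60% gave 100 and 99. These calls used an unadjusted p under 0.05, and marks were drawn independently of CpG content and of neighbouring genes. The simulation therefore did not test linked genes, shorter lists, the adjustment or the effect of CpG matching.

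The gene lists, tests and genes to be named were chosen before the data were examined. The named genes were, in each list, the up to 4 marked members with the largest mean covered share. In lists with over 50% of members marked, up to 3 unmarked members were also named, and in the other lists the marked members where there were 5 or fewer. The genes whose 5′ ends lie in the 10 longest domains, the 10 genes with the highest signal value within 1 kb of the 5′ end, and the maps of the 4 Hox clusters, Pax6, Foxg1, Neurog2 and Gata4 completed the rule. Where other genes are named, the text says that they were chosen after their values were seen.

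Alternatives covered the pooled list in place of the replicated one, the peaks of replicate 1 that overlap replicate 2, each replicate alone, a stricter −log10 q, promoter windows of 0.5 and 2.5 kb, at least 500 bp covered, any annotated transcript start, other overlaps between peaks, and other merging gaps. For the gene lists they also covered 10000 random lists matched on promoter CpG in 20 bins, CpG-rich promoters only, and genes within 100 kb of each other counted as 1 locus. A locus counted as marked when its marked genes were at least as many as its unmarked ones. An analysis of the autosomes alone was added after seeing the data, as was a test of gene families defined by shared symbols. The Y chromosome and unplaced sequences were left out. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.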

Results

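H3K27me3 marks genes that Polycomb complexes keep silent, and its peaks were located here in the forebrain of mouse embryos at embryonic day 13.5. The 2 biological replicates formed 1 group with no second condition. The values therefore describe which genes and regions carried the mark and how far the replicates shared it. Replicate 1 had 103929 peaks and replicate 2 had 80317, a mean of 92123 ± 16696 (SD, n = 2). The peaks covered 46.3 Mb and 39.97 Mb, a mean of 43.1 ± 4.47 Mb (SD, n = 2) or 1.69% ± 0.175 of the assembled sequence. The list of replicated peaks held 51000 peaks over 47.5 Mb, and the pooled list 131687 peaks over 68.0 Mb. Each replicated peak was identical to a peak of the pooled list, and 69.8% of them overlapped peaks in both replicates. The depth of the libraries was unknown.

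The Hox clusters carried the mark over long stretches that both replicates shared. The peaks found in only 1 replicate were shorter and weaker. Of the peaks of replicate 1, 44.8% overlapped a peak of replicate 2, against a mean of 2.75% and a maximum of 3.61% in 100 circular shifts. Of the peaks of replicate 2, 57.2% overlapped a peak of replicate 1, against a mean of 3.40% and a maximum of 4.07%. The shared bases amounted to 56.5% of the bases of replicate 1 and 65.4% of those of replicate 2. Unshared peaks had a median length of 221 bp in replicate 1 and 211 bp in replicate 2, against 380 bp and 353 bp for shared peaks. Their median signal value was 2.67 against 3.13 in replicate 1 and 2.87 against 3.29 in replicate 2. Across the 46539 peaks of replicate 1 with a partner, signal values had a Spearman rho of 0.487 between replicates, and peaks are not independent replicates.

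Of promoters, exons, introns and intergenic sequence, promoters were the most enriched in the mark. Within 1 kb of gene 5′ ends lay 10.04% of the bases under replicated peaks, against 1.60% of the genome, a ratio of 6.27. The shifted peaks gave 1.47% to 2.07%. Exons outside promoters held 9.19% of the peak bases against 4.53% of the genome, and introns 43.5% against 41.8%. Intergenic sequence held 37.3% against 52.0%. In the replicates taken alone the promoter share was 9.72% ± 0.981 (SD, n = 2). A replicated peak marked the promoters of 4107 of 21755 protein-coding genes (18.9%), against a mean of 947 genes and a maximum of 1085 in the shifts. Replicate 1 marked 4654 genes, replicate 2 marked 4318, and both marked 3710.

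CpG-rich promoters were marked more often than CpG-poor ones, but the intermediate class was marked most often. Replicated peaks lay at 2160 of 10077 CpG-rich promoters (21.4%), at 1112 of 3055 intermediate promoters (36.4%) and at 835 of 8623 CpG-poor promoters (9.68%). The rich and poor classes differed with p 1.44e-109 by a two-sided Fisher's exact test. The mean shares over the replicates were 22.1% ± 0.246, 38.4% ± 1.02 and 12.7% ± 2.11 (SD, n = 2), so the order of the classes held by more than the spread between replicates. CpG was measured only at the outermost 5′ end, so a gene whose usual start lies elsewhere may be misplaced. Gata4 and Sox10 were CpG poor there, with ratios of 0.174 and 0.166. The same limit applies to the CpG-matched lists.

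The 4 Hox clusters were covered almost from end to end. All 39 Hox genes had a marked promoter in the replicated list and in each replicate. Between the first and last 5′ end, the covered share was 98.4% ± 0.439 in the Hoxa cluster, 99.0% ± 0.00361 in Hoxc, 97.6% ± 1.17 in Hoxd and 85.7% ± 0.0639 in Hoxb (SD, n = 2). In Hoxb the uncovered stretches lay mainly between Hoxb13 and Hoxb9. Hoxa3, Hoxa5, Hoxa6 and Hoxa7 had the whole of their 10 kb windows under peaks in both replicates.

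**Figure D1:**
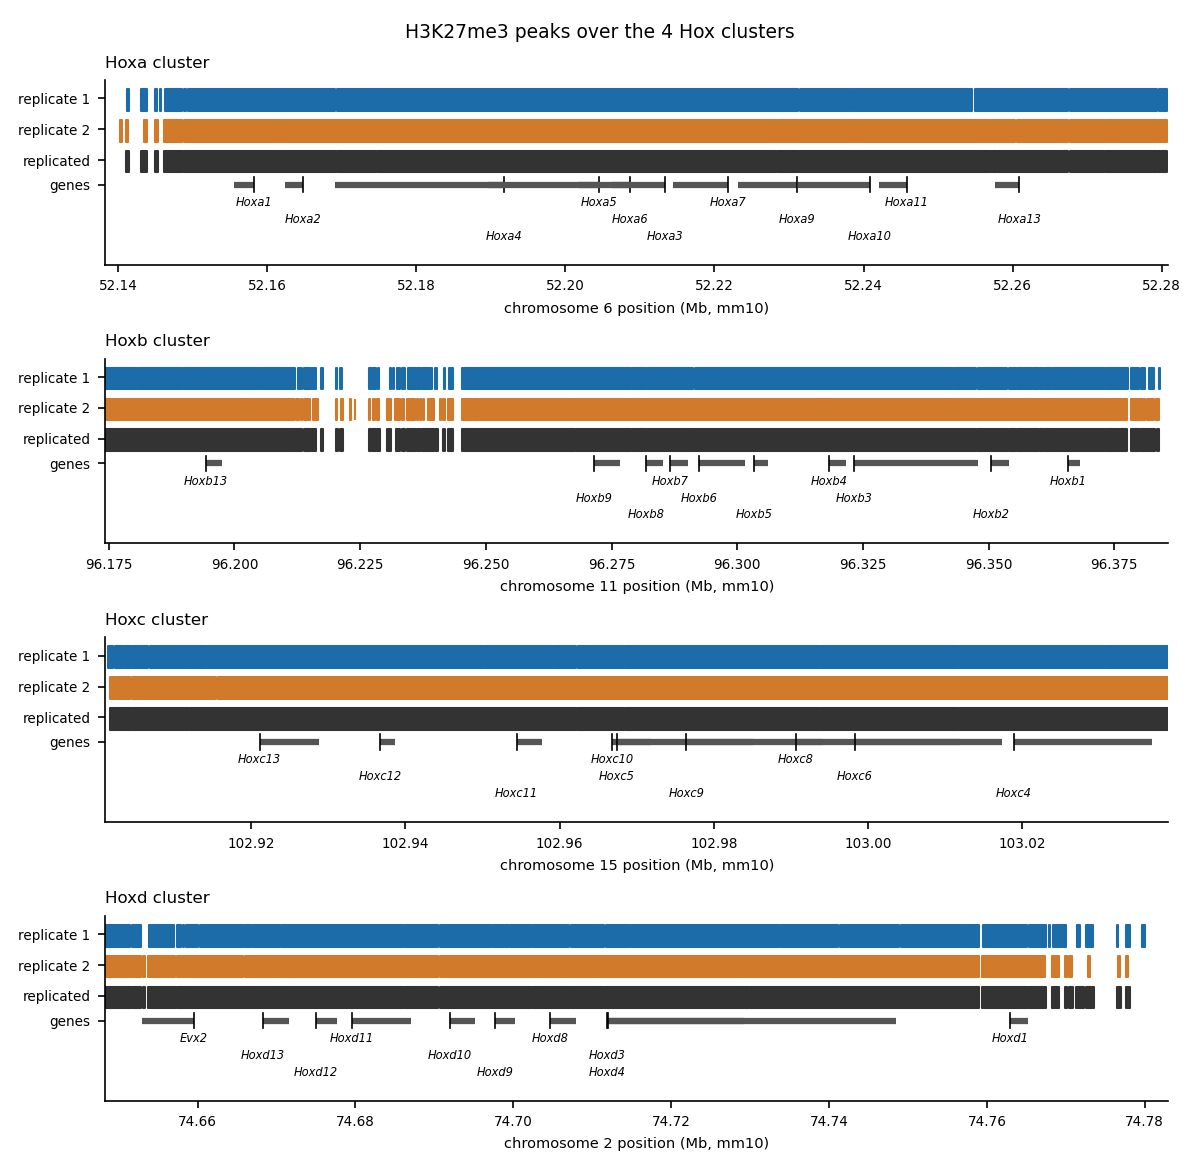
Peaks of replicate 1, replicate 2 and the replicated list along the 4 Hox clusters, with position in Mb on mm10 on the x axis and gene 5′ ends as ticks. Peaks cover 98.4% of Hoxa, 85.7% of Hoxb, 99.0% of Hoxc and 97.6% of Hoxd in the mean of the 2 replicates.

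The longest domains included all 4 Hox clusters, and others lay within the annotated spans of single genes. The longest domain spanned 255 kb over the Hoxc cluster, on chromosome 15 from 102894739 to 103150068. It was followed by the Hoxa cluster with Evx1, on chromosome 6 from 52141024 to 52331675 (191 kb), and by a domain of 165 kb on chromosome 7 that held the 5′ ends of Dbx1 and Htatip2. The next was a domain of 160 kb on chromosome 7 that held the 5′ end of Cdkn1c and overlapped Kcnq1. The Hoxb genes from Hoxb9 to Hoxb1 lay in 157 kb on chromosome 11, and the Hoxd cluster with Evx2 lay in 139 kb on chromosome 2. Domains within the annotated spans of Slit3 (145 kb), Fgfr2 (134 kb) and Agap1 (124 kb) held no 5′ end of a protein-coding gene. Whether read-through transcripts extend these spans beyond the usual gene was not examined. Slit3, Fgfr2, Agap1 and Kcnq1 are named because these domains overlap them, and were chosen after their values were seen. A domain of 123 kb around Nkx2-1 on chromosome 12, from 56425657 to 56549011, completed the 10 longest. Over these 10, the covered share of the replicates ranged from 54.9% ± 0.657 at Slit3 to 91.8% ± 0.779 at Hoxa (SD, n = 2). Of 17309 domains, 94 reached 50 kb, and 30 of these held the 5′ end of a gene on the Hox or homeobox list. The 94 domains held 119 gene 5′ ends, 66 of them of genes on those lists, and 33 held none. The number of such domains depended on the merging gap, with 24 at 1 kb and 302 at 10 kb, and was 211 in the pooled list. Among the 10 longest were 2 Hox clusters at a gap of 10 kb and 3 in the pooled list.

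Transcription factors listed for tissues other than the forebrain were marked more often than other genes, and so were homeobox-type factors, which include forebrain factors. Whether members of the lists for other tissues also act in the forebrain was not examined. All 44 midbrain, hindbrain and spinal cord factors were marked, with a median covered share of 94.1% ± 1.80 (SD, n = 2). Mnx1 (100%), Pax7 (99.5% ± 0.608), Gata2 (99.4% ± 0.127) and Lmx1b (99.1% ± 0.0212) were the most covered. Of the mesoderm, limb and muscle factors 50 of 56 (89.3%) were marked, led by T, Barx1, Pitx1 and Msx2 with 98.8% to 99.4% of their windows covered. Among the 6 unmarked members were Eya1, Myf5 and Myog, while Myod1, chosen after its value was seen, was marked with 61.5% ± 7.34 of its window covered. The endoderm factors were marked at 17 of 25 (68%), with Cdx2 (100%), Neurog3 (98.7% ± 0.622), Foxa2 and Foxa1 on top and Ehf, Elf3 and Elf5 among the unmarked. Of the blood lineage factors 15 of 25 (60%) were marked, led by Tal1 (92.9% ± 1.42), Gfi1, Ikzf3 and Ebf1. Bcl6, Cebpe and Foxp3 were among the unmarked members. The replicates gave 80% and 60% for this list, a mean of 70.0% ± 14.1 (SD, n = 2). Homeobox-type factors outside the Hox list were marked at 110 of 116 (94.8%), with Cdx2, Hmx1, Mnx1 and Nkx1-1 wholly covered. This list shares members with the lists above, such as Mnx1 and Cdx2, and with the forebrain list, such as Six3 and Nkx2-1. Arx, Arxes1 and Arxes2 were among the unmarked members.

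Each of these lists exceeded the other protein-coding genes. By Fisher's exact test with Benjamini-Hochberg adjustment over the 22 lists, the adjusted p was 2.20e-28 for Hox, 8.44e-32 for midbrain, hindbrain and spinal cord factors, and 2.61e-29 for mesoderm, limb and muscle factors. It was 2.99e-07 for endoderm factors, 1.56e-05 for blood lineage factors and 6.66e-71 for homeobox-type factors. The other genes were marked at 18.5% to 18.8% in these comparisons. Over the 22 lists, 13 lay above the other genes, 4 below and 5 showed no call. Against CpG-matched lists, 12 lay above and 3 below.

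**Figure D2:**
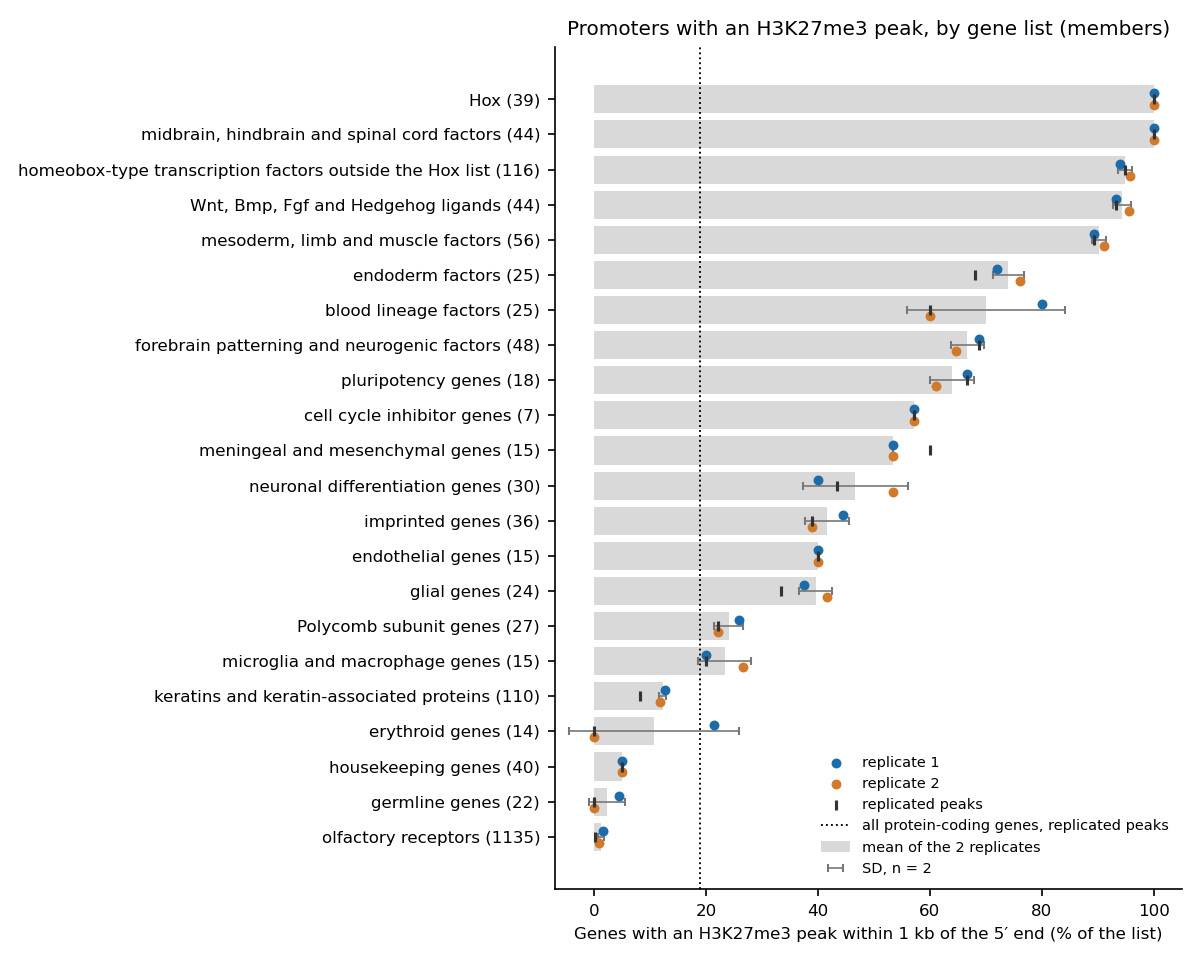
Percentage of genes in each of the 22 lists with an H3K27me3 peak within 1 kb of the 5′ end, with points for the 2 replicates, bars for their mean, whiskers for the SD (n = 2) and ticks for the replicated peaks. Hox genes stand at 100% and olfactory receptors at 0.176% of replicated peaks, against 18.9% for all protein-coding genes (dotted line).

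Factors that build the forebrain itself were marked in part. Some factors classed as confined to one region or cell class, such as Six3 and Nkx2-1, were among the most covered. Others of that class, such as Arx and Emx2, had no promoter peak, and neither had several general factors. Of the 48 forebrain patterning and neurogenic factors, 33 (68.8%) were marked, 66.7% ± 2.95 in the replicates (SD, n = 2). The list lay above the other genes with an adjusted p of 1.95e-13 by Fisher's exact test. Six3 had 99.7% ± 0.361 of its window covered, Neurog1 97.8% ± 0.806, Neurod2 97.4% ± 0.601 and Nkx2-1 96.0% ± 0.587 (SD, n = 2). Arx, Bcl11a and Bcl11b had no promoter peak and 0.875% ± 1.24, 0% and 2.78% ± 1.11 of their windows covered. Sox2, Sox11 and Pou3f3, chosen after their values were seen, had 0% covered in both replicates. Emx2, also chosen afterwards, had no peak within 1 kb of its outermost 5′ end although 50.3% ± 5.15 of its window was covered.

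**Figure D3:**
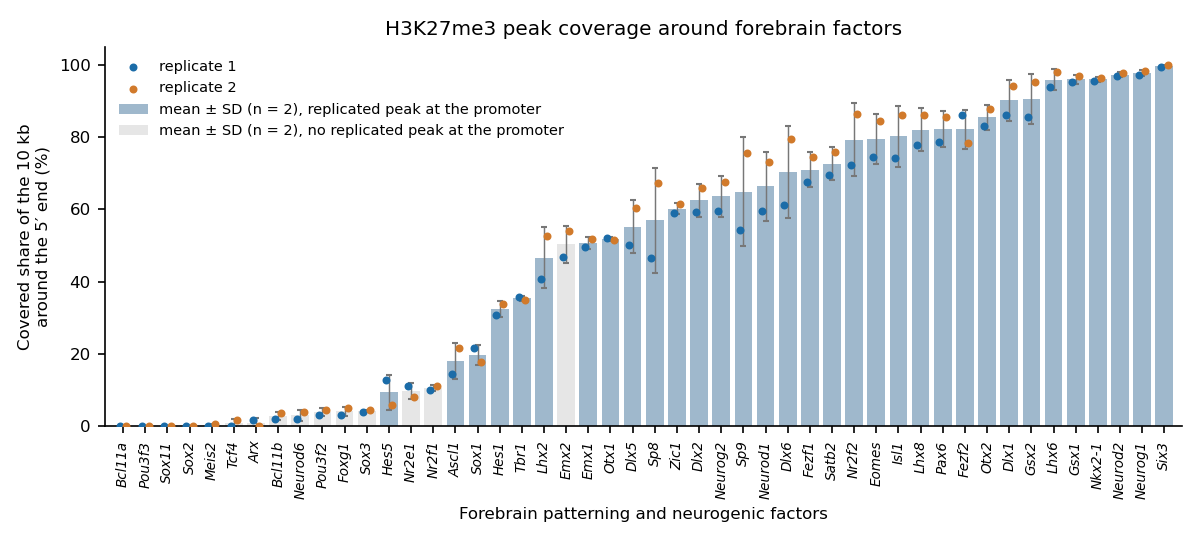
Covered share of the 10 kb around the 5′ end (y axis, %) of each of the 48 forebrain patterning and neurogenic factors, with points for the 2 replicates, bars for their mean and whiskers for the SD (n = 2). Blue bars mark the 33 factors with a replicated peak at the promoter, from 9.31% to 99.7% at Six3.

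The maps of 4 loci fixed beforehand showed these contrasts. Pax6, at 105668900 on chromosome 2, lay under peaks that covered 82.2% ± 4.94 of its window, and Neurog2, at 127633135 on chromosome 3, under peaks covering 63.6% ± 5.66 (SD, n = 2). Foxg1, at 49382660 on chromosome 12, had no promoter peak and 4.04% ± 1.28 of its window covered. Gata4, a mesoderm factor at 63271692 on chromosome 14, had 77.1% ± 1.18 covered.

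**Figure D4:**
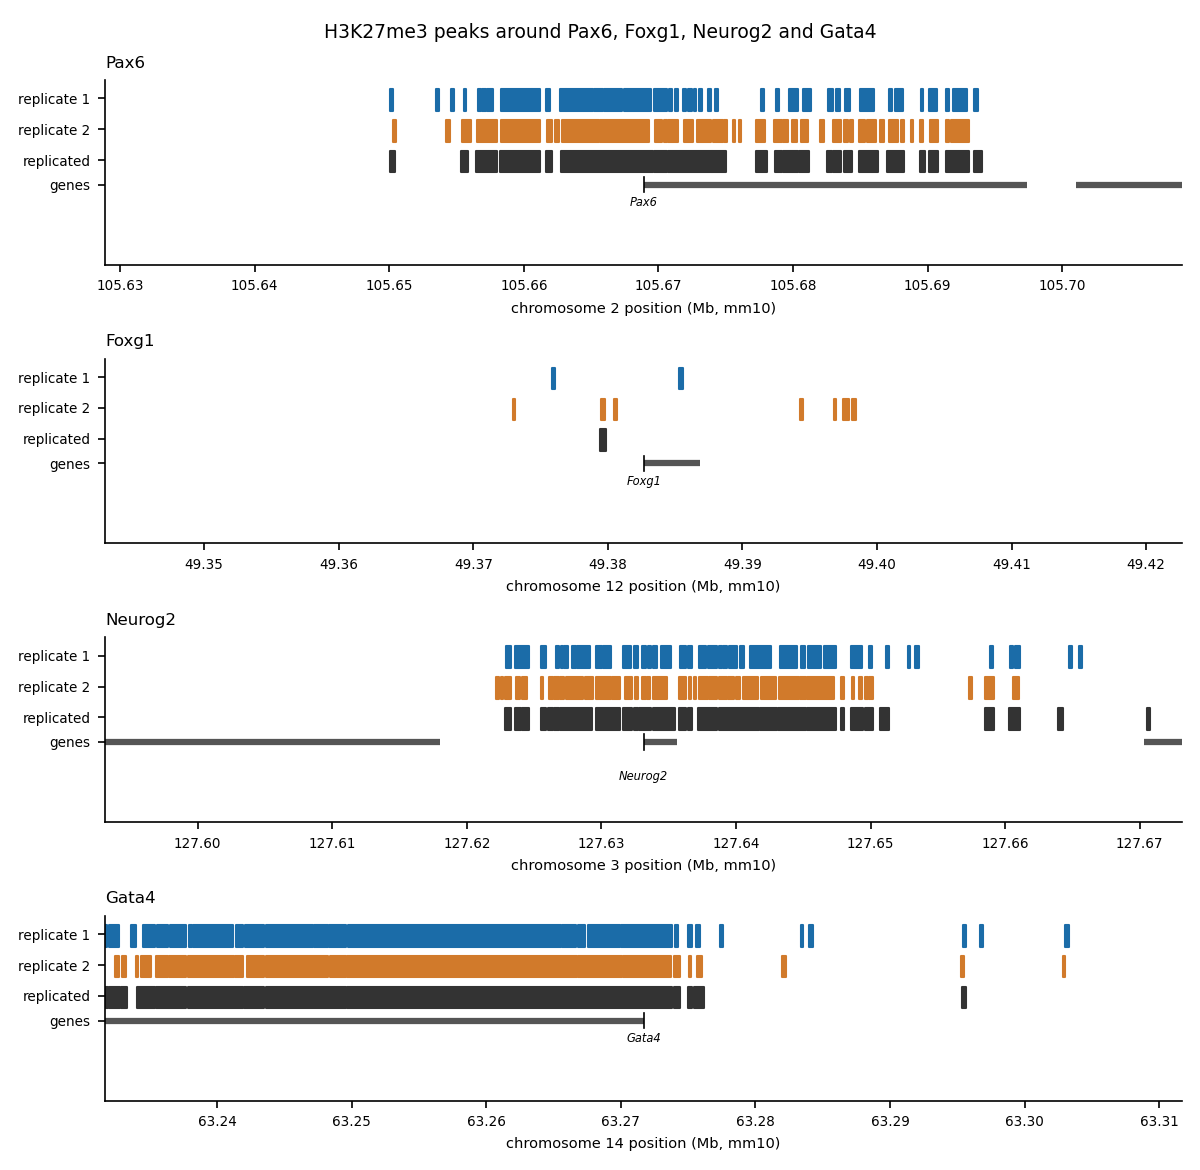
Peaks of replicate 1, replicate 2 and the replicated list around Pax6, Foxg1, Neurog2 and Gata4, with position in Mb on mm10 on the x axis and gene 5′ ends as ticks. Peaks cover 82.2% of the 10 kb around the 5′ end at Pax6, 63.6% at Neurog2 and 77.1% at Gata4, against 4.04% at Foxg1.

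Neuronal differentiation genes and glial genes were marked in part. The neuronal genes with the most coverage encode transmitter transporters, a receptor subunit and an enzyme of GABA synthesis. Slc32a1 had 88.5% ± 5.02 of its window covered, Grin1 70.1% ± 3.05, Slc17a7 62.7% ± 1.65 and Gad2 59.9% ± 10.6 (SD, n = 2). Neuronal differentiation genes were marked at 13 of 30 (43.3%, adjusted p 0.00330 by Fisher's exact test), with 40% and 53.3% in the replicates, and the list's median window coverage was only 6.30% ± 0.0848. With genes within 100 kb counted as 1 locus this call was lost (17.8 points, adjusted p 0.0660, in a range of 1.03e-04 to 0.0660 over all alternatives). Dcx, Map2 and Gap43, chosen after their values were seen, had 0% covered. Glial genes were marked at 8 of 24 (33.3%), which did not pass (adjusted p 0.122), with the oligodendrocyte lineage genes Olig1, Olig2 and Sox10 at 94.4% ± 1.00, 91.6% ± 2.51 and 58.6% ± 1.29 covered and Gjb6 at 41.0% ± 0.445. Replicate 2 alone put the glial list 21.8 points above the other genes, with an adjusted p of 0.0232 in a range of 0.00475 to 0.506 over all alternatives.

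The endothelial, meningeal, erythroid and microglial lists were each compared with the other protein-coding genes, and among these 4 only the meningeal genes passed in the replicated list. The endothelial receptor genes Flt1 and Kdr had 91.4% ± 2.51 and 75.0% ± 3.08 of their windows covered, and Sox18 and Esam 71.7% ± 0.898 and 64.4% ± 1.51 (SD, n = 2). Only 6 of 15 endothelial genes (40%) were marked, with an adjusted p of 0.0582 by Fisher's exact test, and the list passed in 5 of 13 alternatives (adjusted p 0.0156 to 0.234 over all of them). Meningeal and mesenchymal genes were marked at 9 of 15 (60%, adjusted p 9.99e-04), led by Pdgfra, Aldh1a2, Col1a1 and Cyp1b1 with 60.8% to 86.4% of their windows covered, while Col3a1, Col6a3 and Dcn were unmarked. Among CpG-rich promoters the meningeal list kept only 2 members, both marked (78.6 points), and did not pass. Its adjusted p ranged from 8.80e-04 to 0.0623 over all alternatives. None of the 14 erythroid genes was marked in the replicated list, but this list did not pass (adjusted p 0.101), and replicate 1 alone marked 21.4% of it, 0.0358 points above the other genes. Of the microglia and macrophage genes 3 of 15 (20%) were marked, namely C1qc (42.7% ± 6.53 covered), C1qa (33.0% ± 7.52) and Fcgr3 (21.9% ± 2.72), with an adjusted p of 1. Without replicate 2 this list lay on the other side of the background, at -1.39 points.

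Signalling ligands and pluripotency genes were marked far more often than other genes. Of the Wnt, Bmp, Fgf and Hedgehog ligands 41 of 44 (93.2%) were marked, led by Wnt10a, Wnt10b, Wnt6 and Wnt1 at 95.9% to 99.5% covered, and the exceptions were Bmp5, Fgf10 and Fgf20. The list's adjusted p was 4.65e-26 by Fisher's exact test. Pluripotency genes were marked at 12 of 18 (66.7%, adjusted p 2.64e-05), with Tbx3 (96.5% ± 3.03), Utf1 (81.1% ± 1.63), Prdm14 (72.4% ± 10.1) and Pou5f1 (41.6% ± 3.87) on top (SD, n = 2). Dppa2, Dppa3 and Dppa4 were unmarked. The pluripotency list shares Tbx3 with the mesoderm, limb and muscle list and Fgf4 with the ligand list. Germline genes, whose list holds meiotic and piRNA genes, showed the opposite with 0 of 22 marked (adjusted p 0.0330). With replicate 1 alone the germline call was lost, at -16.9 points and an adjusted p of 0.0846, in a range of 0.00477 to 0.103 over all alternatives.

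Cell cycle inhibitors, Polycomb genes and imprinted genes were marked in part. Cdkn2a had 90.8% ± 2.35 of its window covered, Cdkn2b 78.4% ± 3.38, Cdkn1c 68.3% ± 5.32 and Cdkn1a 27.4% ± 1.76 (SD, n = 2), while Cdkn1b, Cdkn2c and Cdkn2d were unmarked. The list of 7 passed narrowly at 57.1% (adjusted p 0.0353 by Fisher's exact test), and without replicate 2 it did not (35.8 points, adjusted p 0.0577, in a range of 0.00993 to 0.170 over all alternatives). Of the Polycomb subunit genes 6 of 27 (22.2%) were marked, with Cbx8 (80.9% ± 1.70), Cbx4 (54.7% ± 1.54), Pcgf1 and Pcgf5 on top and an adjusted p of 0.654. Imprinted genes were marked at 14 of 36 (38.9%, adjusted p 0.00726), led by Dio3 (98.6% ± 0.912), Grb10 (86.8% ± 0.0495), Klf14 and Ascl2. Among CpG-rich promoters 44.4% of 18 imprinted genes were marked against 21.4% of the others (23.1 points), a difference no smaller than the 20.04 points over all promoters, and the call was lost. Its adjusted p ranged from 0.00173 to 0.0544 over all alternatives.

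Genes in constant use and the sensory and skin gene families mostly had no replicated peak at the promoter. The aligner was not given, so how well peaks could be called in families of similar genes is unknown. Housekeeping genes were marked at 2 of 40 (5%, adjusted p 0.0330 by Fisher's exact test), and these were Rpl3 and Ldha with 14.2% ± 2.47 and 7.20% ± 3.68 of their windows covered (SD, n = 2). The housekeeping call was lost in 5 of 13 alternatives, with adjusted p from 0.00249 to 0.137 over all of them. Of 1135 olfactory receptors, only Olfr95 and Olfr222 were marked (0.176%, adjusted p 9.58e-101). Keratins and keratin-associated proteins were marked at 9 of 110 (8.18%, adjusted p 0.00517), led by the epithelial keratins Krt8 (58.6% ± 6.62) and Krt18 (52.8% ± 2.60) with Krt19 and Krt87. In the later Fisher tests of gene families, the keratins alone (Krt) showed no call, at 7 of 53 (13.2%, adjusted p 0.586). The keratin-associated genes (Krtap) were marked at 2 of 57 (3.51%, adjusted p 0.0103). The keratin call was lost against CpG-matched lists (-6.33 points, adjusted p 0.0683), with the pooled list (-8.05 points), and with loci of 100 kb (-23.5 points). With loci the same 9 genes were marked, but they were outnumbered by unmarked genes in each locus, so 0 of 11 loci counted as marked. The larger difference there is therefore no sign of less marking. Its adjusted p ranged from 6.99e-04 to 0.107 over all alternatives.

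Signal values of peaks overlapping the 1 kb on either side of the 5′ end were ranked by their mean over the replicates. The order differed between the replicates. Each value belongs to a whole peak, which can reach beyond the promoter and span several genes. Foxf1 reached 14.7 ± 2.82 and Wnt3a 14.5 ± 4.03 (SD, n = 2). Hoxa3, Hoxa5, Hoxa6, Hoxa7 and the read-through gene model Gm28308 shared a value of 13.9 ± 4.81. Klf14 reached 13.7 ± 2.10, and the neighbouring retinoic acid degrading genes Cyp26a1 and Cyp26c1 reached 13.6 ± 1.92. The formula of the signal value was not stated. Replicate 2 had the higher value at each of these 10 genes, but genes with a common value are not separate observations.

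Chromosomes 19 and 11 were the most covered, and the X chromosome differed between the replicates. Chromosome 19 had 3.12% ± 0.354 of its assembled bases under peaks and chromosome 3, the least covered autosome, 0.913% ± 0.119 (SD, n = 2). Over the autosomes replicate 1 covered 1.90% and replicate 2 covered 1.56%, and the ratio of replicate 2 to replicate 1 lay between 0.795 and 0.851 on all 19. On the X chromosome replicate 1 covered 0.507% and replicate 2 covered 1.52%, a ratio of 2.99. Replicate 2 had 7904 peaks on the X and replicate 1 had 2846. Of the X peaks of replicate 2, 21.3% overlapped a peak of replicate 1, against 61.1% of its autosomal peaks. At the promoters of the 948 protein-coding genes of the X, replicate 1 marked 85, replicate 2 marked 149 and the replicated list 100.

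**Figure D5:**
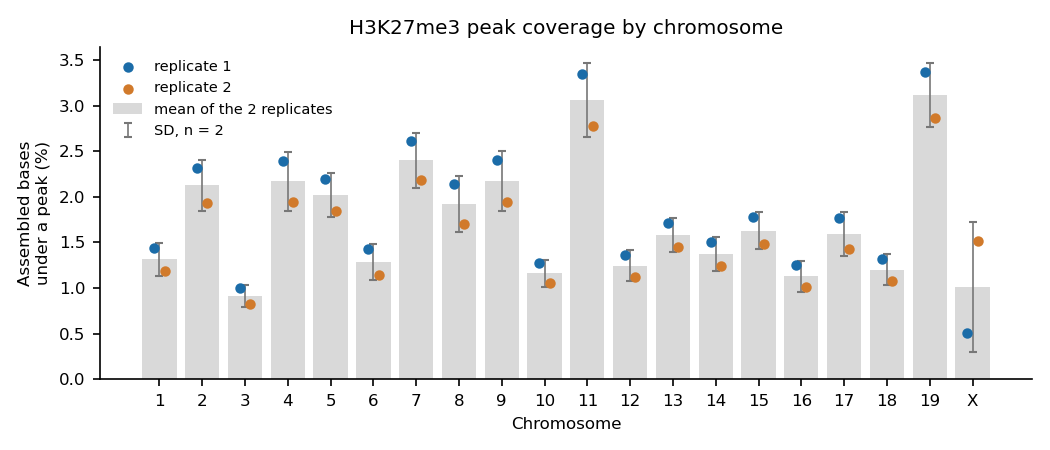
Percentage of assembled bases under H3K27me3 peaks on each chromosome, with points for the 2 replicates, bars for their mean and whiskers for the SD (n = 2). Replicate 2 lies below replicate 1 on all 19 autosomes and above it on the X, where the values are 1.52% and 0.507%.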

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

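The alternatives were fixed before the data were examined except the analysis of the autosomes alone, which was chosen after seeing the data. Of 283 recomputed list comparisons, 236 kept their direction and side of the threshold, 28 lost their call, 10 gained one and 9 changed direction. The lists of Hox genes, forebrain factors, midbrain, hindbrain and spinal cord factors, mesoderm factors, endoderm factors, blood lineage factors, ligands, pluripotency genes, olfactory receptors and homeobox-type factors kept both under each of their 12 to 13 alternatives. The forebrain list ranged from 44.1 to 53.1 points above the other genes.

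The other lists depended on a setting, and where a call or direction changed the cause was not tested. Counting linked genes as 1 locus and keeping CpG-rich promoters left fewer units, so that a call could be lost without a smaller difference. The neuronal and cell cycle lists, at 24.5 and 38.3 points in the main comparison, had smaller differences as well where they lost their calls in this way. The neuronal list itself changed little, from 43.3% of 30 genes to 41.4% of 29 loci. Most of its smaller difference came from a higher marked share among the other genes once counted as loci. The lists are given as percentage points from the other genes. Neuronal genes lost their call with loci of 100 kb (17.8). Glial genes passed with the pooled list (28.9), windows of 2.5 kb (21.4) and 0.5 kb (18.3) and any transcript start (23.9), and with single replicates ranged from 16.1 to 21.8, passing in replicate 2. Endothelial genes passed with the peaks of replicate 1 that overlap replicate 2 (23.9), −log10 q of at least 5 (24.1), windows of 0.5 kb (24.95), at least 500 bp covered (25.7) and CpG-rich promoters (78.6). Meningeal genes (78.6) and imprinted genes (23.1) lost their calls among CpG-rich promoters.

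Housekeeping genes lost their call with the overlapping peaks of replicate 1 (-11.1), −log10 q of at least 5 (-10.9), windows of 2.5 kb (-14.5) and 0.5 kb (-10.1) and at least 500 bp covered (-9.29). Germline genes lost it with the pooled list (-16.2), the overlapping peaks (-16.1), −log10 q of at least 5 (-15.9), windows of 0.5 kb (-15.1), at least 500 bp covered (-14.3), any transcript start (-17.5) and CpG-rich promoters (-21.5), and ranged from -19.9 to -16.9 with single replicates. Cell cycle inhibitors lost it with the pooled list (31.9), the overlapping peaks (26.7), −log10 q of at least 5 (26.99), windows of 2.5 kb (32.7), at least 500 bp covered (28.6), CpG-matched lists (39.3), CpG-rich promoters (28.6) and loci (26.5), and ranged from 35.8 to 37.3 with single replicates. Keratins lost it with the pooled list (-8.05), CpG-matched lists (-6.33) and loci (-23.5). Reversed directions concerned lists without a call. Erythroid genes ranged from -19.9 to 0.0358 with single replicates. Microglia genes fell below the background with windows of 2.5 kb (-4.44) and 0.5 kb (-1.73), at least 500 bp covered (-7.61), any transcript start (-2.001) and loci (-8.14), and ranged from -1.39 to 6.82 with single replicates. Polycomb genes fell below it with windows of 0.5 kb (-0.249) and loci (-3.55). Erythroid genes, olfactory receptors and keratins have no CpG-rich promoters, so that alternative gave no value.

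Peak counts depended on the threshold. At −log10 q of at least 2, replicate 1 kept 64359 peaks. At 5, replicate 1 kept 16458 peaks (20.7 Mb), replicate 2 kept 18524 (22.6 Mb), the replicated list 29571 and the pooled list 32292 (38.1 Mb). Replicate 1 thus had more peaks than replicate 2 as deposited and fewer at 5. The shared percentages of replicate 1 and replicate 2 were 35.2 and 46.3 when 50% of the peak had to overlap, 23.0 and 29.8 when 50% of both did, 51.0 and 53.3 at −log10 q of at least 2, 69.9 and 59.8 at 5, 51.1 and 51.6 with equal numbers of peaks, and 44.3 and 61.1 on the autosomes.

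Domains of 50 kb or more numbered 24 with a gap of 1 kb, 302 with 10 kb and 211 in the pooled list, and 2 Hox clusters stayed among the 10 longest with a gap of 10 kb. The pooled list covered 2.69% of the autosomes and 2.11% of the X. Promoters held 7.97% of the peak bases in the pooled list, 11.5% at −log10 q of at least 5, 23.8% with windows of 2.5 kb, and 9.03% to 10.4% with single replicates. Exons held 8.13%, 10.03% and 6.84% in the first 3 of these. Introns held 43.3% at −log10 q of at least 5, 36.9% with windows of 2.5 kb and 43.2% to 43.3% with single replicates. Intergenic sequence held 40.4% in the pooled list, 35.1% at −log10 q of at least 5, 32.4% with windows of 2.5 kb, and 36.9% to 38.8% with single replicates. The median covered share of the named genes was 95.5% with windows of 2.5 kb on either side. Values of single named genes moved by less than the spread between replicates in 362 cases and by more in 82.

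No paired analysis was possible because there is a single group. The unknown depth limits what a missing peak can show.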

Other observations

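The gene families, the highest autosomal ratio, the genes that escape X inactivation and the forebrain comparison outside the homeobox genes were tests chosen after results had been seen. Families that share a symbol stem were tested when they had at least 8 members. All 19 Wnt, 14 Nkx, 9 Pax and 8 Lhx genes had a marked promoter. The Wnt genes are on the ligand list and the other 3 families on the homeobox list, so these counts repeat marks given above. Of the serotonin receptor (Htr) genes 13 of 14 (92.9%) were marked, with an adjusted p of 2.14e-07 by Fisher's exact test over the 340 families. Metabotropic glutamate receptor (Grm) genes and Shisa genes were marked at 7 of 8 each (87.5%, adjusted p 9.67e-04), synaptotagmin (Syt) genes at 12 of 17 (70.6%, adjusted p 1.09e-04), and calcium channel (Cacna) genes at 9 of 14 (64.3%, adjusted p 0.00355). Some other channel and receptor families passed, namely Gpr (adjusted p 2.66e-04), Fzd (0.00698), Kcnh (0.00975) and Kcnk (0.0137), but Kcnh and Kcnk lost their calls against CpG-matched lists (0.0911 and 0.102). Scn (0.146), Kcna (0.0507), Kcnj (0.0747), Cacng (0.387) and Chrna (0.880) did not pass. Collagen (Col) genes were marked at 28 of 45 (62.2%, adjusted p 1.04e-08). The replicates gave 89.3% ± 5.05 for the Htr genes and 64.4% ± 6.29 for the Col genes (SD, n = 2).

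Other families lay below the background. None of the 331 vomeronasal receptor (Vmn) genes was marked (adjusted p 1.16e-28 by Fisher's exact test), and 27 of 394 Zfp genes were (6.85%, adjusted p 9.71e-10). None of the 67 histone (Hist) genes and 35 Vps genes, 1 of 49 Mrpl genes and 2 of 54 Rpl genes were marked, with adjusted p of 4.57e-05, 0.00975, 0.00841 and 0.0199. The histone genes form only 7 loci when genes within 100 kb are counted together, too few for even 0 marked loci to pass (p 0.211). In all, 34 families lay above the other genes and 13 below. With linked genes counted as 1 locus, 20 and 9 of these kept their calls, but each of the 4 Hox families is then 1 locus, which cannot pass, as the 7 histone loci cannot, so these losses say nothing about their marking. Against CpG-matched lists 24 and 10 kept theirs.

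The X chromosome carried 2.99 times as many covered bases in replicate 2 as in replicate 1, while replicate 2 covered fewer bases on each autosome. A weaker replicate 1 as a whole is argued against, since the highest autosomal ratio was 0.851. A single rearranged or mismapped part of the X is argued against too, since 100% of the 5 Mb windows of the X with any peak were more covered in replicate 2. A shift of every X value, from a different number of X copies or from a different control library, may contribute: at 1782 shared X peaks the median log2 ratio of signal values (replicate 2 over replicate 1) was 0.30, above the range of 0.12 to 0.17 over the autosomes, but an inactive X in female embryos would give this too. Genes that escape X inactivation (Ddx3x, Kdm6a, Eif2s3x, Pbdc1 and Kdm5c) had a mean of 0.114% of the gene body covered in replicate 2, against 4.64% for 250 other X genes with CpG-rich promoters, with a one-sided permutation p of 0.138, and replicate 1 showed the same order (0% against 2.23%); both medians were 0%, the list has only 5 genes, and the share of female embryos in each replicate is not given, so an inactive X cannot be told apart from the other open explanations.

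Forebrain factors were marked in the tissue that uses them, at 33 of 48, and CpG-rich promoters alone are argued against as the cause, since among CpG-rich promoters the list was marked at 70.3% against 21.3% for other genes, a difference of 49.0 points with an adjusted p of 7.93e-10 by Fisher's exact test. Cells of the dissected forebrain that do not express a given factor may carry the mark. Factors classed as restricted to a region or cell class were marked at 25 of 29 (86.2%). Those classed as broadly expressed were marked at 8 of 19 (42.1%), with a one-sided p of 0.00182 by Fisher's exact test. The classes were not drawn from expression data of these samples. Outside the homeobox list the shares were 12 of 14 (85.7%) and 5 of 16 (31.3%, p 0.00354 by the same test). Homeobox genes among the restricted factors are therefore argued against as the whole cause. On the homeobox list the contrast was absent, with 13 of 15 restricted factors (86.7%) and all 3 broad ones (Lhx2, Otx1 and Otx2, named after their values were seen) marked. Expression was not measured here, and a mark present in the same cells that use the factor stays open.

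Some lists above the background hold clustered genes, which are not independent. The 39 Hox genes formed 4 loci and the 36 imprinted genes 23. Most of the lists held few linked genes. The 44 midbrain, hindbrain and spinal cord factors formed 43 loci, the 48 forebrain factors 46 and the 25 blood lineage factors 25. With genes within 100 kb counted as 1 locus, 11 of the 13 lists above the other genes (84.6%) kept their calls, and the neuronal and cell cycle lists lost theirs. Linkage between listed neighbours is therefore argued against as the source of most of these calls. For most lists this rests on how few members were linked, since counting loci hardly changed those lists. Apart from the test on forebrain factors, no biological explanation was tested for these lists.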
